A study of Mus musculus with 9 samples.

How the data were processed

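Livers of mice injected with acetaminophen (APAP) were profiled by RNA sequencing. The labels define 4 groups by genotype (wild type or Adipor2 knockout) and by the injection that followed (saline or leonurine, labelled Leo), with 3 libraries from wild-type mice given saline and 2 in each of the other 3 groups. Leonurine is the alkaloid that the series title calls SCM-198. Total RNA was extracted with TRIzol and libraries were built with a VAHTS universal RNA-seq kit, per the labels' protocols. Each library was placed in its group by its title. Dose, interval between injections, sex and age were not given in the sources used here.

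The authors deposited 1 table of FPKM values (fragments scaled by transcript length and library total) for 16857 genes and all 9 libraries. The submitters' processing notes name fastp, HISAT2, HTSeq, R version 3.2.0 and the mouse build mm10. The role and order of these tools, the gene annotation, any filter on genes and the use of strand were not given in the sources used here. Each library's column was matched to its sample by the RNA number in the sample's description, and 0 numeric columns of the table were left unmatched.

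FPKM divides fragments by gene length and by library total, so that a few very abundant transcripts can lower the values of every other gene in a library. The 10 genes with the most fragments took between 20.5% (labelled knockout, saline, replicate 2) and 30.0% (wild type, leonurine, replicate 2) of a library. Because the values were written with many decimals, the ratio of a gene's values between libraries gave back whole numbers of fragments, up to a factor common to all libraries for a gene. This held for 16857 of 16857 genes at a tolerance of 0.0001. On simulated FPKM the step returned 100.0% of 2958 genes exactly, and called 0.0% of genes whole after a small amount of noise was added. The recovered totals ran from 35316653 to 38996734 fragments per library, a ratio of 1.1 between the highest and the lowest. No pair of libraries was alike within sampling noise, the smallest chi-square per degree of freedom between 2 libraries being 30.8, so each library was counted as 1 replicate.

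Differences were tested with limma version 3.58.1 in R version 4.3.3 on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 of the 9 libraries were tested, which left 10451. A linear model with 1 mean per group was fitted to all 9 libraries, so that the groups of 2 shared 1 estimate of the spread (5 residual degrees of freedom, and 4.4 prior degrees of freedom from the moderated variance with a trend on mean expression). A fold change on this scale understates the change of genes with low FPKM. Where every library of a group was at 0, a lower bound of the fold was computed against 3 fragments over that group, which covers counting error only. The 5 comparisons were leonurine against saline in wild type, leonurine against saline in the labelled knockout, the difference between these responses, and labelled knockout against wild type under saline and under leonurine. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested in a comparison). Standard errors (SE) are those of limma's moderated fit. The level of Adipor2 was compared between 4 and 5 libraries with a two-sided exact permutation test.

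Gene lists for the tissue and the treatment, 36 in all, were fixed before the data were examined, as were the model, the comparisons, the rule for the genes named and all alternatives not described as added later. The 32 lists with at least 4 tested genes were tested with limma's camera, which asks whether the members of a list moved further in 1 direction than other genes, at a preset correlation between genes of 0.01. The test was repeated with an estimated correlation. The lists of lymphocyte and NK cell markers (0 tested genes), platelet genes (2), mitochondrially encoded genes (0) and exocrine pancreas genes (1) were too small. Adjusted p-values for lists are over the lists tested in a comparison. The genes named are Adipor2 and the members of its signalling axis, the 10 called genes with the largest rise and the 10 with the largest fall on log2(FPKM + 1) per comparison whose groups did not overlap, and the 4 members of each described list with the smallest p. Symbols of predicted genes, clones and pseudogenes were passed over. Where fewer than 10 genes were called, the places went to genes with a log2 fold change of at least 1 in size and the smallest p, given as values that did not pass. Outside this rule, Uty, Arntl and, as the 1 clock gene called higher, Nfil3 were chosen after their values were seen. The passes of Pcna, Mcm6 and Ccne2 with the saline libraries alone were also picked out after they were seen. The test of clock activators, which also holds Nfil3, was written before its result was seen.

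The fit was tested on simulated data with 200 changed genes among 10451. Of the genes changed by 1 on the log2 scale it called 77%, 76%, 22%, 83% and 62% in the comparisons as ordered above. Of those changed by 2 it called 100%, 99%, 92%, 100% and 98%. Another 20 genes were shifted together as a list, and false calls among the 10231 genes left unchanged numbered 11, 16, 5, 8 and 8. The real libraries differed in spread (array weights 0.61 to 2.79), so these rates may not hold for them.

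Genome positions are 1-based positions in GRCm38 (mm10) from the GENCODE M21 annotation, matched by gene symbol. Of 16857 symbols, 16280 had 1 position, and of the 10451 tested genes 10281 did. Near-identical family members (the Mup genes, Saa1 and Saa2, Cyp3a41a, Cyp4a12a and Cyp4a12b, the Sult2a genes, Cyp2a4 and Cyp2a5, and the alpha and beta globin genes) can share fragments, and their separate values are uncertain.

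The alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, scaling by the median ratio of each library to the geometric mean, quantile normalization, limma array weights, a robust prior variance, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma voom on the recovered fragments, a fit without both libraries from labelled knockout mice given leonurine and a fit of the saline libraries alone. Also added then were counts without the genes of the sex-biased lists, and the tests of clock genes with Npas2, with each library left out and with quantile normalization. The tables were handled with Python version 3.11.15, numpy version 2.4.6 and pandas version 2.3.3, and figures were drawn with matplotlib version 3.10.9.

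Single-gene results of 4 genes are not reported here, and counts over genes and lists include them.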

Results

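The series title and design text ask whether leonurine, an alkaloid under study as a treatment for acute liver failure, acts through the adiponectin receptor Adipor2 in livers injured by acetaminophen. Expression was measured by RNA sequencing of whole liver in 9 libraries, 3 from wild-type mice given saline and 2 from each of the other 3 groups. All mice had received acetaminophen, so no library shows an uninjured liver. Genes above 0 numbered 14790 (wild type, leonurine, replicate 2) to 15054 (wild type, saline, replicate 1). In the median gene of a library, 3 fragments corresponded to 0.0221 to 0.0246 FPKM, so differences between libraries in depth were small beside those in expression. The labels do not say whether the libraries of a group came from separate animals, and all p-values measure the spread between these samples, which may be technical.

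Adipor2, the targeted gene (chromosome 6, 119353150 to 119417704, minus strand, protein coding), was expressed in every library. Its level was 134.0 ± 7.57 FPKM (SD, n = 3) in wild type given saline, 73.06 ± 4.14 (n = 2) in labelled knockouts given saline, 80.35 ± 6.51 (n = 2) in labelled knockouts given leonurine and 83.34 ± 6.81 (n = 2) in wild type given leonurine. Labelled knockouts given saline thus kept 54.5% of the wild-type saline level, and wild type given leonurine 62.2%. Over all libraries the 4 labelled knockouts lay below the 5 wild-type libraries by 0.53 on the log2 scale, which a two-sided exact permutation test over 126 splits did not separate (p = 0.0556, smallest possible p = 0.0079). That p was 0.0317 after median-ratio scaling (difference -0.58), 0.0159 after quantile normalization (-0.74), 0.0286 without wild type, leonurine, replicate 1 (-0.65) and 0.0357 without labelled knockout, leonurine, replicate 2 (-0.58). The deleted part of the gene is not given in the sources used here, so FPKM over the whole gene neither rules a knockout in nor out, and these mice are called labelled knockouts throughout. With limma, Adipor2 fell with leonurine in wild type (log2 fold change -0.68 ± 0.15 SE, adjusted p = 0.0345). That call ended without any 1 of the wild-type libraries, with an adjusted p of 0.105, 0.107 and 0.131 without saline replicates 1, 2 and 3, and 0.0554 and 0.0777 without leonurine replicates 1 and 2. It also ended with median-ratio scaling (-0.53 ± 0.17, adjusted p = 0.0922), with quantile normalization (-0.33 ± 0.18, adjusted p = 0.306) and with the replicate number as a block (adjusted p = 0.106). Adipor2 did not pass between the saline groups (-0.87 ± 0.15, adjusted p = 0.107), but passed with the saline libraries alone (0.0435). It did not pass between the leonurine groups (-0.05, adjusted p = 0.876), with leonurine in the labelled knockout (0.13, adjusted p = 0.661) or for the difference between the responses (0.81 ± 0.23, adjusted p = 0.0834).

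The other genes of the axis named in the series title were examined next. Calm2 and Calm3 (calmodulin), Camk2b and Camk2g (subunits of the kinase CaMKII), the endothelial nitric oxide synthase Nos3 and the related receptor Adipor1 passed the test in 0 of the 5 comparisons. Camk2b came closest, at 1.198 ± 0.50 FPKM (SD, n = 3) in wild type and 2.906 ± 0.116 (n = 2) in labelled knockouts under saline (log2 fold change 0.85 ± 0.18 SE, adjusted p = 0.148). Camk2a and Camk2d were below the filter on low values. Nos3 was between 1.234 and 2.405 FPKM in the 9 libraries, a level at which log2(FPKM + 1) understates fold changes. On the axis list of 15 tested genes, which did not pass as a list in wild type given leonurine (adjusted p = 0.635), 2 downstream genes besides Adipor2 fell in either count. Prkaa2, a catalytic subunit of AMP kinase, fell by 0.88 (± 0.13 SE, adjusted p = 0.0096), a call that ended without saline replicate 3 (0.0505) or leonurine replicate 2 (0.0611). Ppara, the receptor that drives fatty acid oxidation, fell by 0.94 (± 0.22, adjusted p = 0.0407), a call that ended without saline replicate 1 (0.0936), 2 (0.111) or 3 (0.138), leonurine replicate 2 (0.266) or either labelled knockout saline library (0.0596 for each), with median-ratio scaling (0.0649), with quantile normalization (0.0664) and with no filter on low values (0.096).

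The libraries also differed in transcripts that mark sex. Ddx3y (chromosome Y, 1260771 to 1286629), Kdm5d and Uty were at 0 in both libraries from labelled knockouts given leonurine, where Ddx3y was 10.16 to 14.73 FPKM in the other 7 libraries. Fragments from Ddx3y, Eif2s3y, Kdm5d and Uty together numbered 0 and 2 in these 2 libraries against 4154 to 5275 in the others. Cyp2b9, a cytochrome P450 with female-biased expression in mouse liver, was 255.4 and 171.8 FPKM in these 2 libraries and at most 5.177 in the other 7. This difference runs through every comparison that uses the labelled knockouts given leonurine.

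**Figure D1:**
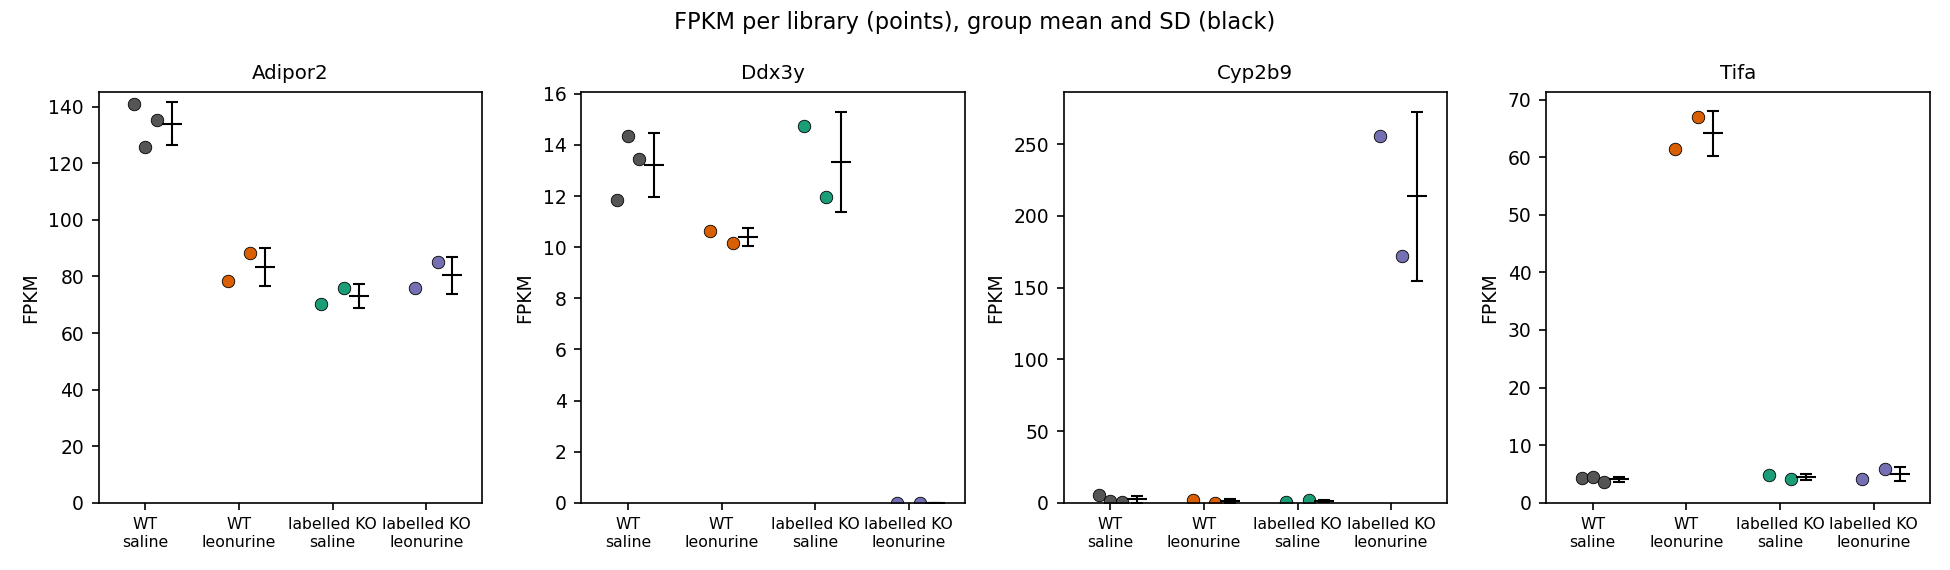
FPKM of Adipor2, Ddx3y, Cyp2b9 and Tifa in each library (points) by group, with the group mean and SD in black. Adipor2 has a mean of 73.06 to 83.34 FPKM in 3 of the 4 groups and 134.0 in wild type given saline. Ddx3y is at 0 and Cyp2b9 at 255.4 and 171.8 in the labelled knockouts given leonurine, and Tifa is at 61.41 and 66.95 in wild type given leonurine.

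The first comparison was leonurine against saline in wild type. Of 18 genes of the acute phase response, which hepatocytes secrete or express in inflammation, 15 rose, and the list did not pass with an estimated correlation (adjusted p = 0.138). Lcn2 (lipocalin-2, an iron-scavenging protein of the response to infection; chromosome 2, 32384633 to 32388252) went from 337.3 ± 182 FPKM (SD, n = 3) with saline to 6123 ± 2650 (n = 2) with leonurine. Tifa, an adaptor in NF-kB signalling (chromosome 3, 127789805 to 127832164), went from 4.087 ± 0.464 to 64.18 ± 3.92 FPKM. In the other direction, Car3 (carbonic anhydrase 3; chromosome 3, 14863512 to 14872523) went from 727.6 ± 197 to 16.06 ± 20.2 FPKM, and Thrsp, a regulator of fatty acid synthesis (chromosome 7, 97412938 to 97417730), from 192.2 ± 27.0 to 7.17 ± 3.07. Ciart and Dbp, outputs of the circadian clock, fell as well.

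Of the 18 acute phase genes tested, 15 rose over all genes and 18 when adjusted over the list alone, and 0 fell. The list stood 2.03 above the median of all tested genes (camera, adjusted p = 4.78e-24, or 0.138 with an estimated correlation). Lcn2 rose by 4.24 ± 0.46 (SE) on the log2 scale (adjusted p = 0.0023), the serum amyloid P component Apcs by 2.78 ± 0.40 (adjusted p = 0.00731) and ceruloplasmin (Cp) by 1.25 ± 0.18 (adjusted p = 0.00759). Saa3 rose by 6.74 ± 1.06 (adjusted p = 0.0102), with 312 and 2112 FPKM in the leonurine libraries, and its call ended without leonurine replicate 2 (5.36, adjusted p = 0.0778). Other genes among those with the largest rise were Serpina3n (3.36 ± 0.35, adjusted p = 0.00209), the interleukin-1 receptor antagonist Il1rn (3.12 ± 0.51, adjusted p = 0.011) and Cd14, a co-receptor for bacterial lipopolysaccharide (3.08 ± 0.32, adjusted p = 0.00209). A2m, a protease inhibitor, was 9.579 and 933 FPKM in the leonurine libraries and at most 0.2367 with saline (adjusted p = 0.0288). Its call ended without saline replicate 1, 2 or 3 (adjusted p = 0.0684, 0.0887 and 0.0874).

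Among the other genes with the largest changes, Sult1e1, which sulfates estrogens, rose by 3.99 ± 0.29 (SE) on the log2 scale (adjusted p = 0.000335). Inmt, which methylates small amines, fell by 6.21 (± 0.74, adjusted p = 0.00361). Cyp2a5, a P450 that oxidises coumarin, fell by 5.72 (± 0.90, adjusted p = 0.0102), and the sulfotransferase Sult2a8 fell by 3.76 (± 0.61, adjusted p = 0.011).

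Markers of neutrophils stood 1.36 above the median gene (adjusted p = 1.8e-06, or 0.487 with an estimated correlation). Of these, 3 of 8 rose over all genes (6 adjusted over the list alone), with Ngp (neutrophilic granule protein) at 0.3461 and 7.781 FPKM under saline and leonurine. Metallothioneins and related metal-binding genes stood 2.16 above it (adjusted p = 0.000142, or 0.138 with an estimated correlation), and 3 of 5 rose (4 adjusted over the list alone). Among them Mt1 was at 151.5 and 1078 FPKM, but its call ended without saline replicate 2 (adjusted p = 0.0762) or 3 (0.0757) or leonurine replicate 2 (0.147). Of 10 cytokine and chemokine genes 0 were called over all genes and 3 adjusted over the list alone. That list passed (adjusted p = 0.00575, or 0.558 with an estimated correlation), but not without leonurine replicate 1 (median -0.10, adjusted p = 0.203), with median-ratio scaling (0.0503) or with quantile normalization (0.0716). The lymphocyte markers were too low to test. The list median of neutrophil markers, 1.24, was 1.95 without leonurine replicate 2, and that of metallothioneins, 2.03, was 1.33 without saline replicate 2.

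Of 13 genes that metabolise acetaminophen, 9 fell over all genes and 10 adjusted over the list alone, where 1 rose, and the list stood -1.07 from the median gene (adjusted p = 0.000497, or 0.558 with an estimated correlation). The glutathione transferase Gstm1 went from 1941 to 219.5 FPKM, Cyp1a2 from 373.4 to 84.83 and Cyp2e1, the main enzyme that activates acetaminophen, from 2466 to 1198. These 3 calls ended without leonurine replicate 2 (adjusted p = 0.0732, 0.211 and 0.266) and without saline replicate 3 (0.0639, 0.107 and 0.131). Those of Cyp1a2 and Cyp2e1 also ended without saline replicate 1 (0.0666 and 0.0909) or 2 (0.113 and 0.181), and that of Cyp2e1 without either library of each labelled knockout group (0.0584, 0.0586, 0.0602 and 0.0601), with a pseudocount of 0.1 (0.0531), with median-ratio scaling (0.085) and with array weights (0.0615). Of 14 targets of the antioxidant regulator Nrf2, 6 fell (9 adjusted over the list alone) and 0 rose (adjusted p = 0.000382, or 0.558 with an estimated correlation). Among them Gclc, which catalyses the limiting step of glutathione synthesis, fell by 2.13 on the log2 scale (± 0.29 SE, adjusted p = 0.0064). Bile acid genes fell in 3 of 15 members (9 adjusted over the list alone, adjusted p = 0.000923, or 0.487 with an estimated correlation). Heat shock genes fell in 2 of 11 (7 adjusted over the list alone, adjusted p = 0.000923, or 0.558 with an estimated correlation). Without leonurine replicate 2 the list medians of acetaminophen metabolism and Nrf2 targets were -0.78 and -0.52, against -1.19 and -0.89 with all libraries, and without saline replicate 2 that of heat shock genes was -0.58, against -1.04.

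Clock genes changed in both directions. Of 13 tested, 6 fell and 1, Nfil3, rose by 1.39, a call that ended without any 1 wild-type library or labelled knockout saline library (adjusted p = 0.0385, then 0.0555 to 0.223), and adjusted over the list alone 10 fell and 1 rose. The list stood -1.02 from the median gene (adjusted p = 0.000497, or 0.558 with an estimated correlation). Ciart fell by 2.69 (± 0.29 SE, adjusted p = 0.00214) and Dbp fell by 3.25 (± 0.45, adjusted p = 0.00669). Genes of fat synthesis fell in 5 of 19 (9 adjusted over the list alone), led by Thrsp (-4.61 ± 0.40, adjusted p = 0.000756) and the desaturase Scd1 (-5.68 ± 0.94, adjusted p = 0.0114, but 0.0953 without leonurine replicate 2). Their list test (adjusted p = 0.0436, or 0.756 with an estimated correlation) ended without saline replicate 2 (adjusted p = 0.097), leonurine replicate 1 (0.932), either labelled knockout leonurine library (0.0529 and 0.053) or both (0.0529, a fit added after seeing the data), and at a mean FPKM of at least 5 (0.169). Subunits of the mitochondrial respiratory chain stood -0.39 from the median gene with 0 of 17 called over all genes and 9 adjusted over the list alone (adjusted p = 0.000923, or 0.687 with an estimated correlation), and their list median of -0.51 was -0.27 without leonurine replicate 2. Fatty acid oxidation genes fell in 2 of 22 in each count, led by Acaa1b, and their test (adjusted p = 0.00933, or 0.756 with an estimated correlation) ended without leonurine replicate 2 (adjusted p = 0.259), while the list median of -0.55 was -0.93 without leonurine replicate 1. Male-biased liver genes also fell in 4 of 13 (7 adjusted over the list alone, adjusted p = 0.000247, or 0.331 with an estimated correlation), led by Hsd3b5 (-4.37 ± 0.46, adjusted p = 0.00209), while the 4 Y-linked members did not pass. Of 8 erythroid genes 1 fell, Alas2 (3 adjusted over the list alone, adjusted p = 0.0177, or 0.631 with an estimated correlation).

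In all, 692 of 10451 genes were called, 199 higher and 493 lower (28.8% higher). The median gene lay at -0.123 under the deposited scaling, and median-ratio scaling moved it to 0.002, with 328 genes higher and 408 lower (44.6% higher), while quantile normalization gave 402 higher and 435 lower (48.0%). The 2 leonurine libraries stood apart from each other. On the first principal component of log2(FPKM + 1) (38.3% of the variance) replicate 2 was at 52.2, replicate 1 at 26.4 and the 3 saline libraries at -5.6 to -0.8. The chi-square per degree of freedom between recovered fragments was 328.9 between the 2, against 228.1 to 319.2 between replicate 1 and the saline libraries. The number of calls was 354, 152 and 147 without saline replicates 1, 2 and 3, 155 without leonurine replicate 2 (86 higher and 69 lower, 55.5% higher) and 1351 without leonurine replicate 1 (221 and 1130, 16.4%). Without saline replicates 2 and 3 the share called higher was 40.1% in each. Of 75 genes that the naming rule took and that were called here, 23 kept their call whichever library was left out, among them Lcn2, Tifa, Serpina3n, Il1rn, Cd14, Apcs, Cp, Ngp, Car3, Thrsp, Gclc, Hsd3b5, Alas2, Ciart and Dbp. With no filter on low values 25 of the 75 kept their call. Among those that ended were Saa3 (adjusted p = 0.0602), A2m (0.105), Il1rn (0.0623), Cyp2a5 (0.0593), Scd1 (0.0648), Sult2a8 (0.0608), Acaa1b (0.0529), Gstm1 (0.0719), Cyp1a2 (0.111), Mt1 (0.0818) and Cyp2e1 (0.164).

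**Figure D2:**
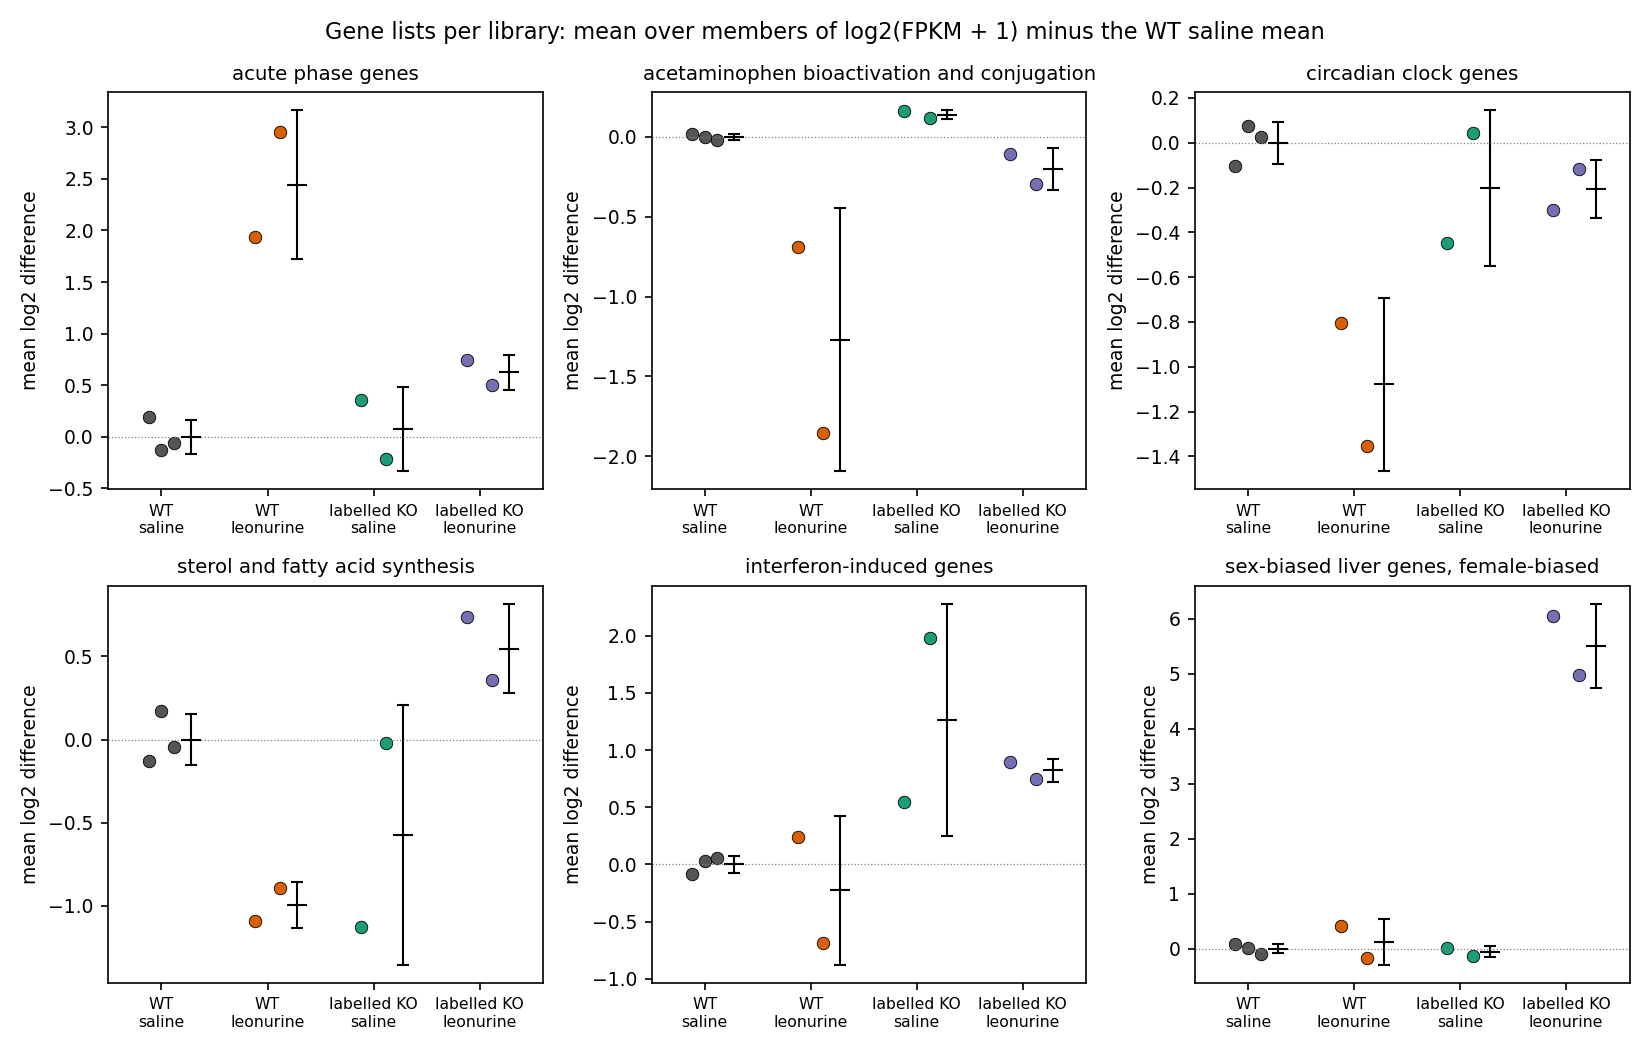
Mean over the members of 6 gene lists of log2(FPKM + 1) minus the wild-type saline mean, per library (points), with the group mean and SD in black. Acute phase genes are higher and acetaminophen metabolism, clock and fat synthesis genes lower in both wild-type libraries given leonurine, and female-biased genes stand apart in both labelled knockout libraries given leonurine.

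The same question was put to the labelled knockouts, where the leonurine libraries lacked Y-linked transcripts (0 and 2 fragments) and the saline libraries held 5275 and 4841. Sex-biased genes led this comparison. Cyp2a4 (chromosome 7, 26307169 to 26315088), a female-biased cytochrome P450, went from 2.623 ± 0.149 to 740.2 ± 438 FPKM (SD, n = 2 each). Cyp3a41a (chromosome 5, 145694049 to 145720136) went from 0 to 143.9 FPKM, at least 7080-fold higher against a floor of 3 fragments over the group. Mup7 (chromosome 4, 60066469 to 60070475), of the male-biased major urinary protein family, went from 2055 ± 798 to 1.462 ± 0.231 FPKM, although fragments of these paralogs can be shared between members.

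Of 10 female-biased genes tested, 8 rose (9 adjusted over the list alone) and 0 fell, and the list stood 6.56 above the median gene (adjusted p = 2.98e-36, or 0.0266 with an estimated correlation). All 13 male-biased genes fell in both counts, and that list stood -2.87 from the median gene (adjusted p = 1.45e-22, or 0.026 with an estimated correlation). The list medians, 6.38 and -3.05, were the same with the genes at 0 in a group set to their floor. Cyp2b9 rose by 6.52 ± 0.65 (SE) on the log2 scale (adjusted p = 0.000706) and Cyp2d9, a male-biased P450, fell by 4.70 (± 0.27, adjusted p = 1.97e-05). Ddx3y was at least 1600-fold lower. Of the 20 genes with the largest changes, A1bg, the sulfotransferase Sult2a2 and the hepcidin paralog Hamp2 rose, and Mup1, Mup12, Mup14, Mup15, Mup17, Mup20, Cyp4a12a and Hsd3b5 fell. The call of Hamp2 ended without labelled knockout saline replicate 1 (adjusted p = 0.0846) or 2 (0.0505).

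Other lists moved in these libraries alongside the Y-linked and female-biased transcripts (Ddx3y at 0, Cyp2b9 at 213.6 ± 59.1 FPKM, SD, n = 2). Genes of sterol and fat synthesis stood 1.19 above the median gene (adjusted p = 1.58e-18, or 0.256 with an estimated correlation), with 1 of 19 called higher and 9 adjusted over the list alone. Their list median of 1.01 was 0.64 without labelled knockout saline replicate 1 and 1.55 without saline replicate 2. The called gene, Thrsp, was at 133.6 and 527.5 FPKM, and its call ended without any 1 library of these groups except labelled knockout saline replicate 2 (adjusted p = 0.138 without saline replicate 1, and 0.106 and 0.113 without leonurine replicates 1 and 2) and without any 1 wild-type saline library (0.0693, 0.0687 and 0.0745). Neutrophil markers stood 1.18 above it with 1 of 8 called higher, Ngp (3 adjusted over the list alone, adjusted p = 5.98e-07, or 0.283 with an estimated correlation). Genes of gluconeogenesis and amino acid breakdown stood 0.68 above (adjusted p = 7.15e-06, or 0.256 with an estimated correlation) and periportal genes 0.69 above (adjusted p = 0.000466, or 0.256 with an estimated correlation). The periportal member Cdh1, E-cadherin, fell from 9.674 to 1.282 FPKM. Hal, a histidine-degrading enzyme and member of both lists, was called higher at 58.75 and 133.2 FPKM. The calls of Hal and Ngp each ended without several libraries, with the highest adjusted p without labelled knockout saline replicate 1 (0.171 and 0.201). These list counts were 1 of 13 (2 adjusted over the list alone) and, for periportal genes, 1 higher and 1 lower of 14 (3 and 1 adjusted over the list alone). Hepatocyte identity genes stood 0.30 above with 0 of 20 called in either count (adjusted p = 0.000226, or 0.417 with an estimated correlation). With quantile normalization the periportal and hepatocyte identity lists did not pass (adjusted p = 0.0721 and 0.118). The list median of neutrophil markers, 1.0, was 1.54 and 0.46 without labelled knockout leonurine replicates 1 and 2, and without replicate 2 that of gluconeogenesis was 0.22, against 0.50, and that of hepatocyte identity 0.19, against 0.12. Without labelled knockout saline replicate 1 the periportal median was 0.26, against 0.50.

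Acute phase genes stood 0.61 above the median gene with 1 of 18 called, Orm3 (1 adjusted over the list alone, adjusted p = 1.15e-05, or 0.34 with an estimated correlation), and without labelled knockout saline replicate 2 the list did not pass (adjusted p = 0.06). Erythroid genes (adjusted p = 7.94e-05, or 0.307 with an estimated correlation) also lost their call without that library (adjusted p = 0.062), with Ahsp higher and Alas2 lower among 8 in either count. Cell cycle genes stood -1.02 from the median gene (adjusted p = 0.000155, or 0.598 with an estimated correlation), with 1 of 20 called, Ccne1 (7 adjusted over the list alone), and did not pass without labelled knockout leonurine replicate 2 (adjusted p = 0.198). Targets of p53 stood -0.63 from the median gene (adjusted p = 0.00088, or 0.532 with an estimated correlation), with 1 of 14 called, Ccng1 (8 adjusted over the list alone), and did not pass without labelled knockout leonurine replicate 1 (adjusted p = 0.0863). Cytokines were called in 0 of 10 in either count (adjusted p = 0.000466, or 0.283 with an estimated correlation). Complement genes were called in 2 of 17 (C9 lower and F7 higher, the same in either count, adjusted p = 0.000858, or 0.283 with an estimated correlation). Both lists lost their calls without labelled knockout leonurine replicate 2 (adjusted p = 0.0577 and 0.382). Metallothionein genes (0 of 5 called, 2 adjusted over the list alone, adjusted p = 0.00868, or 0.256 with an estimated correlation) lost theirs without labelled knockout saline replicate 2 (0.105) or leonurine replicate 2 (0.0867), with median-ratio scaling (0.077) and with quantile normalization (0.101). Monocyte markers (0 of 9 in either count, adjusted p = 0.0357, or 0.417 with an estimated correlation) lost theirs without either wild-type leonurine library (0.0725 and 0.0727), labelled knockout saline replicate 2 (0.142) or leonurine replicate 2 (0.592), with median-ratio scaling (0.142), with quantile normalization (0.126) and at a mean FPKM of at least 5 (0.523). Complement genes also lost theirs with quantile normalization (0.0703). Without labelled knockout leonurine replicate 1 the list medians of cell cycle, erythroid, metallothionein and monocyte genes were -1.93, 0.33, 0.82 and 0.21, against -1.21, 0.93, 0.48 and 0.02 with all libraries. The erythroid median was 1.41 without leonurine replicate 2, and without saline replicate 1 those of cytokines and monocyte markers were 0.37, against 0.60, and 0.10. The calls of Orm3, Ahsp, Alas2, Ccne1, Ccng1, C9 and F7 each ended without several libraries. Their highest adjusted p came without labelled knockout saline replicate 1 (0.109, 0.125, 0.174, 0.148, 0.138, 0.175 and 0.191).

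In the labelled knockouts 219 of 10451 genes were called, 63 higher and 156 lower (28.8% higher). The median gene lay at -0.186, which median-ratio scaling moved to -0.017 with 116 higher and 91 lower (56.0% higher) and quantile normalization to -0.01 with 99 higher and 93 lower (51.6%). The count was 136, 133 and 118 without wild-type saline replicates 1, 2 and 3, 92 without labelled knockout saline replicate 1, 155 without saline replicate 2 (47.7% higher), and 198 without the genes of the sex-biased lists, a count added after seeing the data. Of 43 named genes called here, 26 kept their call whichever library was left out, all of them sex-biased list members or genes named among the 20 largest changes except Cdh1 and the bile acid carrier Slco1a1. With no filter on low values 28 of the 43 kept their call, and those of Hamp2 (adjusted p = 0.058), Thrsp (0.105), Hal, Ngp, Orm3, Alas2, Ahsp, Ccne1, Ccng1, C9 and F7 were among those that ended. With voom those of Hamp2 (0.117), Hsd3b5 (0.0735) and Cyp4a12a (0.0508) were among 10 that ended.

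The difference between these responses was tested directly. Thrsp, of the fat synthesis list, and Ciart, of the clock list, were among the genes that differed. Thrsp went from 192.2 to 7.17 FPKM in wild type and from 133.6 to 527.5 in the labelled knockout, a difference of 6.78 ± 0.59 (SE) on the log2 scale (adjusted p = 0.000479). Ciart went from 12.97 to 1.281 and from 9.324 to 12.33 (3.11 ± 0.43, adjusted p = 0.00701). Rgs16, a regulator of G protein signalling, went from 23.49 to 2.712 and from 4.292 to 84.66 (7.20 ± 0.86, adjusted p = 0.00353). Btg3, an antiproliferative gene, went from 8.019 to 37.82 and from 6.334 to 1.366 (-3.72 ± 0.43, adjusted p = 0.00277). The groups contrasted here also differed in Ddx3y, which was 13.34, 13.21 and 10.4 FPKM in the other 3 groups and 0 in the labelled knockouts given leonurine. Cyp2a4 and Mup7 differed as well (10.04 and -8.81 on log2(FPKM + 1), a scale that understates changes of genes near 0, such as Cyp3a41a).

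Female-biased genes differed in 8 of 10 members (9 adjusted over the list alone, median 6.40, adjusted p = 4.92e-18, or 0.122 with an estimated correlation) and male-biased genes in 9 of 13 (10 adjusted over the list alone, median -2.30, adjusted p = 6.19e-12, or 0.115 with an estimated correlation). Sterol and fat synthesis genes responded more positively in the labelled knockout in 7 of 19 members (10 adjusted over the list alone, median 1.67, adjusted p = 6.19e-12, or 0.405 with an estimated correlation). Acute phase genes responded less in the labelled knockout, with 1 of 18 called, Lcn2 (12 adjusted over the list alone, median -1.84, adjusted p = 1.06e-06, or 0.405 with an estimated correlation). Clock genes differed in 2 of 13, Ciart and Dbp (7 higher and 2 lower adjusted over the list alone, median 1.21, adjusted p = 0.000526, or 0.419 with an estimated correlation), with a list median of 0.78 without labelled knockout saline replicate 1. Erythroid genes differed in 1 of 8 (6 adjusted over the list alone, median 1.65, adjusted p = 3.69e-05, or 0.405 with an estimated correlation). The difference in Y-linked fragments stands beside each of these lists.

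Further lists passed with few called members. Acetaminophen metabolism genes responded more positively in 1 of 13 (3 adjusted over the list alone, median 0.94, adjusted p = 0.00219, or 0.531 with an estimated correlation). Periportal genes differed in 2 higher and 1 lower of 14 (8 and 2 adjusted over the list alone, median 1.0, adjusted p = 0.00108, or 0.405 with an estimated correlation). Bile acid genes differed in 2 of 15 (7 higher and 2 lower adjusted over the list alone, median 0.73, adjusted p = 0.00525, or 0.419 with an estimated correlation). Gluconeogenesis genes were higher in 2 of 13 (4 adjusted over the list alone, median 0.60, adjusted p = 0.000355, or 0.405 with an estimated correlation) and hepatocyte identity genes in 0 of 20 (4 adjusted over the list alone, median 0.54, adjusted p = 0.000623, or 0.523 with an estimated correlation). Cell cycle genes were lower as a list (0 of 20 in either count, median -1.46, adjusted p = 5.91e-05, or 0.665 with an estimated correlation). Respiratory chain genes (0 of 17 in either count, median 0.35, adjusted p = 0.00219, or 0.737 with an estimated correlation) did not pass without labelled knockout saline replicate 2 (adjusted p = 0.141). Nrf2 targets (1 of 14, and 2 adjusted over the list alone, median 0.50, adjusted p = 0.0454, or 0.737 with an estimated correlation) did not pass without wild-type saline replicate 2 (0.056) or 3 (0.0583), wild-type leonurine replicate 2 (0.275), labelled knockout saline replicate 2 (0.141) or leonurine replicate 1 (0.111). With quantile normalization the bile acid, respiratory chain and Nrf2 lists did not pass (adjusted p = 0.0604, 0.107 and 0.148), nor did the Nrf2 list with median-ratio scaling (0.0642), with the replicate number as a block (0.0728) or at a mean FPKM of at least 5 (0.107). Endothelial markers (1 of 13 in either count, median 0.22, adjusted p = 0.0317, or 0.523 with an estimated correlation) did not pass without wild-type saline replicate 2 (0.0531), wild-type leonurine replicate 2 (0.0506) or labelled knockout leonurine replicate 2 (0.0796), with no filter on low values (0.0832) or at a mean FPKM of at least 5 (0.0608).

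The medians of several of these lists moved with 1 library. Without wild-type leonurine replicate 2 those of acetaminophen metabolism, bile acid, gluconeogenesis, hepatocyte identity and respiratory chain genes were 0.18, 0.38, 0.38, 0.21 and 0.15. Without wild-type leonurine replicate 1 those of acetaminophen metabolism, respiratory chain, Nrf2, endothelial and cell cycle genes were 1.72, 0.63, 0.87, 0.39 and -0.81. Without labelled knockout saline replicate 1 those of bile acid, respiratory chain and Nrf2 genes were 0.47, 0.54 and 0.30. Without labelled knockout leonurine replicate 1 cell cycle genes had -2.21 and gluconeogenesis genes 0.93, and without replicate 2 these were -0.77 and 0.30, with 0.54 for the respiratory chain. Gluconeogenesis genes had 0.35 without wild-type saline replicate 1.

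Responses differed for 391 of 10451 genes, 179 more positive in the labelled knockout and 212 more negative (45.8% more positive), and for 374 without the genes of the sex-biased lists. Median-ratio scaling gave 366 and 229 (61.5%), and quantile normalization 308 and 236 (56.6%). The count was 226, 125 and 139 without wild-type saline replicates 1, 2 and 3, 829 and 258 without wild-type leonurine replicates 1 and 2 (67.6% and 41.5% more positive), 108 without labelled knockout saline replicate 1 (45.4%) and 209 without labelled knockout leonurine replicate 1 (33.0%). Without labelled knockout saline replicate 2 the share was 57.8%. Of 45 named genes called here, 24 kept their call whichever library was left out, among them Thrsp, Ciart, Rgs16 and Btg3. The call of Lcn2 ended without wild-type saline replicate 2 (adjusted p = 0.105) or 3 (0.0847), wild-type leonurine replicate 2 (0.0955), labelled knockout saline replicate 1 (0.129) or either labelled knockout leonurine library (0.0731 and 0.0951). The call of Dbp ended without wild-type saline replicate 2 (0.0591) or 3 (0.058), either labelled knockout saline library (0.0779 and 0.0558) or leonurine replicate 1 (0.0681). Among the genes with the largest differences, the call of Scd1 (7.58, adjusted p = 0.0224) ended without wild-type saline replicate 2 (0.0603) or 3 (0.0502), wild-type leonurine replicate 2 (0.0653) or labelled knockout leonurine replicate 1 (0.0694). That of Cxcl14 (-3.77, adjusted p = 0.029) ended without wild-type saline replicate 2 (0.076) or 3 (0.0711), wild-type leonurine replicate 2 (0.0674), labelled knockout saline replicate 1 (0.101) or leonurine replicate 1 (0.0866). Those of Inmt (7.54, adjusted p = 0.00933) and Scara5 (-4.20, adjusted p = 0.0117) ended without labelled knockout saline replicate 1 (0.0506 and 0.0512). With no filter on low values 23 of the 45 kept their call, and those of Hamp2 (0.056), Scd1 (0.0926), Inmt (0.056), Mup20 (0.0553), Lcn2 (0.124) and Dbp (0.0887) were among those that ended. That of Hamp2 also ended with voom (0.104) and that of Lcn2 with array weights (0.0953).

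Across genes, the leonurine responses of the 2 genotypes had a Pearson's r of 0.001 and a Spearman's rho of -0.083 over 10451 genes, which are not independent replicates. The 2 responses share no library. Of the 692 genes called in wild type, 379 (54.8%) had the same sign in the labelled knockout. Genes called higher in both numbered 3, against 1.2 for independent lists, and genes called lower in both numbered 18, against 7.4. Genes called higher in wild type and lower in the labelled knockout numbered 7, and those called in the opposite order 7, against 3 for independent lists in each case. Ngp was called higher and Alas2 lower in both genotypes, although in the labelled knockout both calls ended without saline replicate 1 (adjusted p = 0.201 and 0.174).

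**Figure D3:**
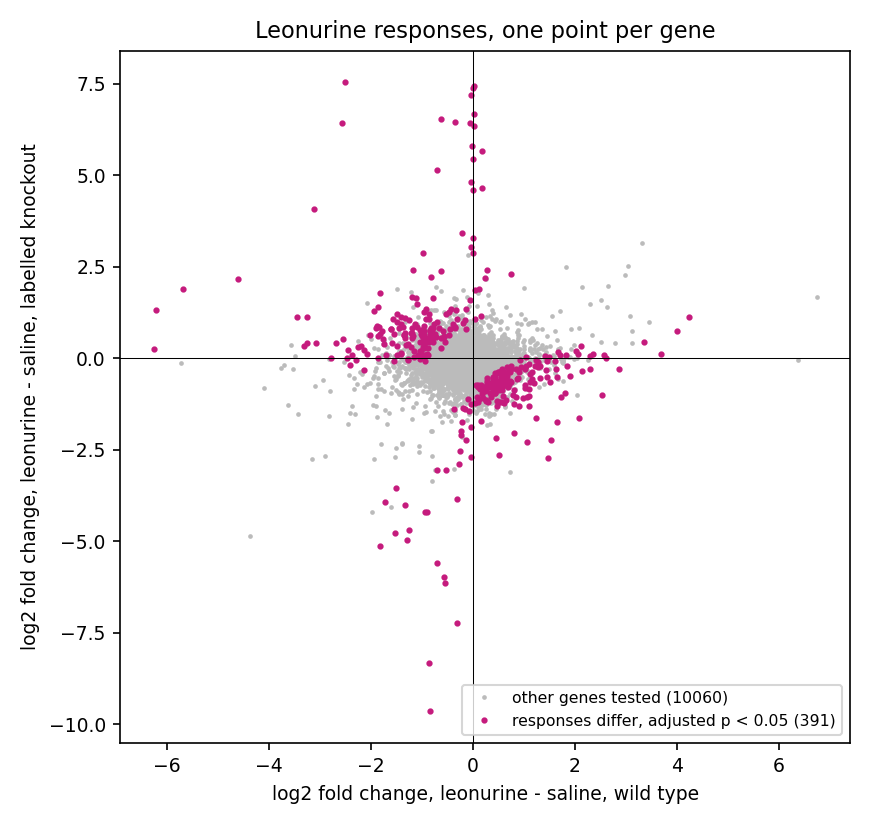
Log2 fold change of leonurine against saline in wild type (horizontal) and in the labelled knockout (vertical), with 1 point per tested gene and the 391 genes whose responses differed in colour. The points form no diagonal (Pearson's r = 0.001).

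The genotypes were next compared under saline, where Y-linked fragments were present in every library (4476 to 5275). Few differences were called with all 9 libraries. With the saline libraries alone the 50 genes with the smallest p passed (adjusted p = 0.0209 to 0.0435). By the same chi-square, labelled knockout saline replicate 2 was nearer the 3 wild-type saline libraries (71.9 to 88.6 per degree of freedom) than labelled knockout saline replicate 1 (118.9). Zfp979, a zinc finger gene (chromosome 4, 147611937 to 147642513), was 0.1189 ± 0.0559 FPKM (SD, n = 3) in wild type and 1.796 ± 0.353 (n = 2) in the labelled knockout. As lists, interferon-induced genes stood higher and immediate early genes lower in the labelled knockout, with 0 members of either called over all genes, and neither list passed with an estimated correlation (adjusted p = 0.735 and 0.628). The interferon list median of 1.25 was 0.42 without labelled knockout saline replicate 2 and 2.13 without replicate 1. Isg15, an interferon-induced ubiquitin-like protein, was 15.05 and 77.74 FPKM in the 2 labelled knockout libraries and 4.787 to 5.535 in the 3 wild-type libraries. It was not called (log2 fold change 2.54, adjusted p = 0.148), but passed without labelled knockout saline replicate 1 (3.69, adjusted p = 0.0163).

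Zfp979 rose by 1.32 ± 0.14 (SE) on the log2 scale (adjusted p = 0.025 in limma). Its call ended without wild-type saline replicate 1, 2 or 3 (adjusted p = 0.142, 0.134 and 0.159), labelled knockout saline replicate 1 (0.0694) or either labelled knockout leonurine library (0.0634 and 0.0609), with a pseudocount of 0.1 (0.146) and with voom (0.07). Genes with the next smallest p that did not pass included Serpine2 (1.38 ± 0.19, adjusted p = 0.0673), Lpin1 (-1.74 ± 0.29, 0.0956), Dusp1 (-1.22 ± 0.19, 0.0864) and Mup17 (2.43 ± 0.35, 0.071). With the saline libraries alone Serpine2, Lpin1 and Mup17 passed (0.0435, 0.0365 and 0.0435). Of 16 interferon-induced genes 0 were called over all genes and 12 adjusted over the list alone, and the list median was 1.25 (adjusted p = 1.21e-08, or 0.735 with an estimated correlation). Of 10 immediate early genes 0 were called and 3 were lower adjusted over the list alone (median -0.72, adjusted p = 1.52e-07, or 0.628 with an estimated correlation, and median -0.40 without labelled knockout saline replicate 2). Cell cycle genes were higher as a list with 0 of 20 called in either count (median 0.84, adjusted p = 0.000252, or 0.769 with an estimated correlation).

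The other lists that passed under saline were lower in the labelled knockout and each lost its call without 1 library. Sterol and fat synthesis genes had 0 of 19 called in either count (median -0.63, adjusted p = 5.85e-07, or 0.735 with an estimated correlation). Clock genes had 0 of 13 called in either count (median -0.14, adjusted p = 0.015, or 0.769 with an estimated correlation). Neither list passed without labelled knockout saline replicate 1 (adjusted p = 0.198, median 0.06, and 0.268). Without labelled knockout saline replicate 2, the lists of gluconeogenesis (0 of 13 in either count, adjusted p = 0.00227, or 0.735 with an estimated correlation), fatty acid oxidation (0 of 22 in either count, adjusted p = 0.00374, or 0.769 with an estimated correlation) and the endoplasmic reticulum stress response (0 of 16, and 1 adjusted over the list alone, adjusted p = 0.00326, or 0.735 with an estimated correlation) did not pass (adjusted p = 0.176, 0.788 and 0.0561). Clock genes did not pass with quantile normalization either (0.0578). Without labelled knockout saline replicate 1 the medians of gluconeogenesis and fatty acid oxidation were -0.42 and -0.31, against -0.26 and -0.16, and without replicate 2 those of fat synthesis and clock genes were -0.98 and -0.28. Gluconeogenesis had -0.16 without wild-type saline replicate 1 and fatty acid oxidation -0.09 without wild-type saline replicate 3.

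Under saline 2 of 10451 genes were called with limma, 1379 had an unadjusted p under 0.05, and limma voom on the recovered fragments called 1, which was not Zfp979. The count was 0 without any 1 of the 3 wild-type saline libraries (1051, 744 and 990 genes at an unadjusted p under 0.05) or of the labelled knockout leonurine libraries (1554 and 1553), 7 without either wild-type leonurine library, and 9 and 18 without labelled knockout saline replicates 1 and 2.

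The genotypes were last compared under leonurine, with Ddx3y at 0 in the labelled knockout and at 10.64 and 10.16 FPKM in wild type. As lists, acute phase genes were lower and fat synthesis and erythroid genes higher in the labelled knockout, none of which passed with an estimated correlation (adjusted p = 0.358, 0.496 and 0.358). Lcn2 was 6123 ± 2650 FPKM (SD, n = 2) in wild type and 806 ± 194 (n = 2) in the labelled knockout, and Thrsp was 7.17 ± 3.07 and 527.5 ± 11.5. Car3 was 16.06 ± 20.2 and 848.6 ± 391 FPKM. The bile acid enzyme Cyp7a1, which catalyses the rate-limiting step, was 2.889 FPKM in wild type and 60.56 in the labelled knockout. Cyp2a4 was at 1.384 FPKM in wild type and 740.2 in the labelled knockout, and Mup7 at 570.2 and 1.462.

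Of 18 acute phase genes, 12 were lower (15 lower and 1 higher adjusted over the list alone, median -1.73, adjusted p = 5.03e-08, or 0.358 with an estimated correlation), with Lcn2 at -2.87 ± 0.50 (SE, adjusted p = 0.0088). Of 19 sterol and fat synthesis genes, 9 were higher (12 adjusted over the list alone, median 1.2, adjusted p = 2.77e-06, or 0.496 with an estimated correlation), with Thrsp at 6.07 ± 0.44 (adjusted p = 8.09e-05) and Srebf1, a master regulator of lipid synthesis, at 2.35 ± 0.32 (adjusted p = 0.00324). Of 8 erythroid genes, 6 were higher (7 adjusted over the list alone, median 1.95, adjusted p = 5.24e-06, or 0.358 with an estimated correlation), mostly globin paralogs such as Hbb-bs at 55.47 and 337.5 FPKM. Of 14 periportal genes, 7 were higher and 2 lower (9 and 2 adjusted over the list alone, median 0.82, adjusted p = 0.00261, or 0.358 with an estimated correlation). Female-biased genes were higher in 8 of 10 (9 adjusted over the list alone, median 6.37, adjusted p = 2.6e-14, or 0.194 with an estimated correlation) and male-biased genes lower in 9 of 13 (11 adjusted over the list alone, median -2.11, adjusted p = 9.35e-14, or 0.0818 with an estimated correlation). Y-linked fragments were 4174 and 4154 in the wild-type libraries and 0 and 2 in the labelled knockouts, beside all of these groups.

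Acetaminophen metabolism genes were higher in 4 of 13 (5 adjusted over the list alone, median 0.83, adjusted p = 0.00227, or 0.585 with an estimated correlation), among them Ugt1a1 (1.68 ± 0.27 SE, adjusted p = 0.00601). Interferon-induced genes were higher in 2 of 16 (5 adjusted over the list alone, median 1.15, adjusted p = 0.000208, or 0.605 with an estimated correlation). Hepatocyte identity genes were higher in 4 of 20 in either count (median 0.61, adjusted p = 0.00502, or 0.585 with an estimated correlation). Respiratory chain genes were higher in 1 of 17 (0 adjusted over the list alone, median 0.52, adjusted p = 0.000743, or 0.605 with an estimated correlation). Metallothionein genes were lower in 1 of 5 in either count (median -1.51, adjusted p = 0.0215, or 0.358 with an estimated correlation). The remaining lists that passed each lost their call without 1 library. Without labelled knockout leonurine replicate 2 this held for bile acid genes (6 higher and 1 lower of 15, and 7 and 3 adjusted over the list alone, adjusted p = 0.0301, then 0.155, or 0.585 with an estimated correlation). It held for clock genes too (5 higher and 2 lower of 13, and 8 and 2 adjusted over the list alone, adjusted p = 0.0215, then 0.288, or 0.585 with an estimated correlation). Without labelled knockout leonurine replicate 1 it held for immediate early genes (4 of 10 lower in either count, adjusted p = 0.00784, then 0.0613, or 0.496 with an estimated correlation). Endoplasmic reticulum stress genes lost theirs without the same library (1 higher and 2 lower of 16, and 1 and 5 adjusted over the list alone, adjusted p = 0.0129, then 0.149, or 0.496 with an estimated correlation). Pericentral genes (3 of 14 higher, 4 adjusted over the list alone, adjusted p = 0.0354, or 0.68 with an estimated correlation) lost theirs without labelled knockout leonurine replicate 1 (0.0993) or wild-type leonurine replicate 2 (0.106). Matrix genes (1 of 14 lower in either count, adjusted p = 0.0301, or 0.585 with an estimated correlation) lost theirs without labelled knockout leonurine replicate 1 (0.113) or wild-type leonurine replicate 1 (0.166). Cell cycle genes (1 of 20 lower, 0 adjusted over the list alone, adjusted p = 0.0286, or 0.746 with an estimated correlation) lost theirs without wild-type leonurine replicate 1 (0.628) or labelled knockout leonurine replicate 2 (0.99, with a median of 0.18).

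With quantile normalization the respiratory chain, bile acid and pericentral lists did not pass under leonurine (adjusted p = 0.109, 0.169 and 0.169). At a mean FPKM of at least 5 the interferon, immediate early, matrix and cell cycle lists did not (0.075, 0.211, 0.865 and 0.096), nor clock genes with no filter on low values (0.138). Without wild-type leonurine replicate 2 the medians of acetaminophen metabolism, interferon-induced, hepatocyte identity and respiratory chain genes were 0.24, 0.55, 0.30 and 0.22, that of bile acid genes was 0.36, against 0.59, and that of cell cycle genes -1.12, against -0.50. Without wild-type leonurine replicate 1 acetaminophen metabolism had 1.45, and pericentral genes 0.95, against 0.49. Without labelled knockout leonurine replicate 1 the respiratory chain had 0.33 and cell cycle genes -1.18.

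Under leonurine 1280 of 10451 genes were called, 731 higher and 549 lower in the labelled knockout (57.1% higher), and 1263 without the genes of the sex-biased lists. The count was 335 without labelled knockout leonurine replicate 1 (51.9% higher), 572 and 1554 without wild-type leonurine replicates 2 and 1 (47.0% and 73.7%), and 593 with array weights. Of 100 named genes called here, 43 kept their call whichever library was left out, among them Lcn2, Thrsp, Srebf1, Car3, Ugt1a1, Ciart, Dbp and the 4 globin genes. With no filter on low values 61 of the 100 kept their call and with array weights 70. The call of Cyp7a1 (log2 fold change 4.11) ended without labelled knockout leonurine replicate 1 (3.29, adjusted p = 0.0569).

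Across genes, the genotype differences under saline and under leonurine had a Pearson's r of 0.034 and a Spearman's rho of 0.128 over 10451 genes, which are not independent replicates. Of the 2 genes called under saline, 0 had the same sign under leonurine, where Zfp979 was at most 0.07053 FPKM in the 4 libraries.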

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

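Of the tests below, those of X-linked genes and of clock activators were written before their results were seen, and the tests of Y-linked fragments, of the origin of the libraries, of scaling, of clock activators below the filter and of clock activators with each library left out were chosen only after the result was seen.

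A direct test of the difference between the leonurine responses of the 2 genotypes passed for 391 genes. The log2 differences of the genes named were 10.04 for Cyp2a4, 9 for Hamp2, 7.58 for Scd1, 7.54 for Inmt, 7.43 for Sult2a2, 7.36 for Sult2a1, 7.21 for Cyp3a41a, 7.20 for Rgs16, 7.15 for Cyp2b9 and 6.81 for Cyp2c69. On the negative side they were -8.81 for Mup7, -7.46 for Mup14, -6.92 for Mup1, -5.60 for Mup12, -5.43 for Mup15, -4.89 for Mup17, -4.20 for Scara5, -3.77 for Cxcl14, -3.72 for Btg3 and -3.67 for Mup20. The calls of Scd1, Inmt, Scara5 and Cxcl14 each ended without 1 library, at an adjusted p of up to 0.0694, 0.0506, 0.0512 and 0.101. List medians that differed were 0.94 for acetaminophen metabolism, 0.50 for Nrf2 targets, 0.54 for hepatocyte identity, 1.0 for periportal genes, 0.73 for bile acid genes, 1.67 for sterol and fat synthesis and 0.60 for gluconeogenesis. Others were -1.84 for acute phase genes, 0.22 for endothelial markers, 1.65 for erythroid genes, -1.46 for cell cycle genes, 0.35 for the respiratory chain, 1.21 for clock genes, 6.40 for female-biased and -2.30 for male-biased genes. None of these lists passed with an estimated correlation.

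In both libraries from labelled knockouts given leonurine, Y-linked transcripts were at or near 0 and female-biased liver transcripts were high. A response of male liver to the treatment is argued against, since Y-linked fragments were 0.0214% of the mean of the other 7 libraries. A candidate explanation is that these mice were female, which the labels do not state. The test of it written in advance, on the X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, gave a median log2 difference of 0.03 (-0.23 to 0.25, exact permutation p = 0.81), on the side of its bound of 0.1 that speaks against female mice. That bound took no account of the spread of these genes (SE 0.1), a criterion added only after the value was seen, so the test decides neither way, and whether the libraries came from wild-type mice stays open too, where 40% of 50 genes that separated the saline groups were nearer the labelled knockout (95% interval 26.4 to 54.8 if the genes were independent, which was not tested).

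Adipor2 was as low in wild-type libraries given leonurine as in the labelled knockouts. Scaling by the abundant acute phase transcripts of these libraries stays open as the cause. The log2 fold change of -0.68 (± 0.15 SE, adjusted p = 0.0345) was -0.53 ± 0.17 with median-ratio scaling (adjusted p = 0.0922), below the bound of -0.35 set for this test, but -0.33 ± 0.18 with quantile normalization (adjusted p = 0.306), above it, and the call ended in both since the change was smaller and its SE slightly larger. Whether these libraries came from knockout mice stays open too. Of the 50 genes, 80% were nearer wild type given saline (66.3 to 90, again if independent), but these genes were picked for differing between 3 and 2 libraries and include Adipor2 itself, so the share decides nothing. A lowering of Adipor2 by leonurine is the biological explanation that the design gives, and it was not tested apart from these.

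Clock output genes were low and acute phase genes high in wild-type libraries given leonurine. Scaling is argued against, since with median-ratio scaling the median log2 fold change of 6 clock outputs was -1.27 (-1.57 to -0.97), and with quantile normalization -1.26. Another time of day at collection could lower the outputs and would raise genes of the opposite phase. Of these, Nfil3, Clock and Cry1 could be tested and had a median of 0.23 (-0.35 to 1.39), between its bounds of 0 and 0.5. With Npas2, which was planned but lay below the filter (0.01818 and 0.6015 FPKM with leonurine, at most 0.05862 with saline), the median was 0.28, or 0.76 with a pseudocount of 0.1, and Arntl, also below the filter, was 0.2518 and 0.7803 FPKM against at most 0.09644. The genes do not agree. Nfil3, at 12.07 and 13.51 FPKM against at most 5.569, rose by 1.39 (adjusted p = 0.0385, lost without any 1 wild-type library). Cry1 was lower (-0.35) and did not pass. Arntl, higher in both libraries, and Npas2 were not tested. Since the median lies between its bounds, another time of day is neither shown nor excluded. The time of collection is not given in the sources used here. An effect of leonurine or of inflammation on the clock therefore cannot be told apart from another time of day.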

How the results depend on the processing

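Voom, the fit without both labelled knockout leonurine libraries and the fit of the saline libraries alone were added only after the data were seen. The counts without the genes of the 2 sex-biased lists were added then too, and leave in other genes called sex-biased here, such as Cyp2a4 and Mup17. The other alternatives in this part were fixed before the data were examined. A library left out of a group of 2 leaves 1, which is assumed to vary like the other groups.

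Leonurine in wild type (692 genes) gave 202 with no filter on low values and 147 to 1351 with each library left out. Leonurine in the labelled knockout (219) gave 136 at a mean FPKM of at least 5, 111 with array weights and 92 to 317 with each library left out. The difference between responses (391) gave 133 with no filter, 595 with median-ratio scaling, 209 with array weights and 108 to 829 with each library left out. Genotypes under leonurine (1280) gave 593 with array weights and 335 to 1554 with each library left out. With no filter more genes are tested and with a library left out fewer samples, and otherwise the cause was not tested. The counts with a pseudocount of 0.1, quantile normalization, a robust prior and voom were within 1.5 times of these 4.

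Under saline the 2 calls of limma became 1 with a pseudocount of 0.1, at a mean FPKM of at least 5 or with voom. Median-ratio scaling gave 4 and quantile normalization 5. Without both labelled knockout leonurine libraries there were 0 (1553 at an unadjusted p under 0.05), but at least 50 in saline libraries alone.

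With the replicate number as a block, the counts were 75 for leonurine in wild type, 124 in the labelled knockout, 102 for the difference, 0 under saline (1226 at an unadjusted p under 0.05) and 889 under leonurine. The numbers do not pair the libraries, since deviations of libraries with the same number had correlations of 0.02 to 0.154, and groups shared at most 2 numbers. Of the named genes called, 15 of 75, 30 of 43, 27 of 45, 0 of 2 and 80 of 100 kept their call with this block. In wild type those of Adipor2, Prkaa2, Ppara, Saa3, A2m, Il1rn, Apcs, Cp, Ngp, Mt1, Cyp2a5, Scd1, Sult2a8, Acaa1b, Gstm1, Cyp1a2, Cyp2e1, Alas2 and Dbp ended (adjusted p = 0.0513 to 0.147). In the labelled knockout those of Thrsp, Hal, Ngp, Alas2, Ahsp, Ccng1, C9 and F7 ended (0.0551 to 0.0973), and under saline that of Zfp979 (0.271). For the difference 18 ended, among them Scd1 (0.0781), Lcn2 (0.087) and Dbp (0.077), and 17 of the 20 genes with the largest differences kept theirs.

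The difference in Adipor2 between labelled knockouts and wild type was -0.58 with median-ratio scaling and -0.74 with quantile normalization, where it passed, and -0.65 to -0.44 with each library left out (exact permutation p = 0.0286 to 0.0571). The correlation of leonurine responses was 0.029 with no filter and -0.044 to 0.048 with each library left out, and that of genotype differences -0.058 to 0.11. The cause was not tested.

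Of 2769 values of lists under alternatives, 2533 kept their side of the threshold and, where called, their direction in camera, 137 lost the call, 94 gained one and 5, all with 1 library left out, turned direction in camera with a call in 1 of the 2 fits. Of 13512 values of named genes these were 12237, 1014, 261 and 0, where a turn again needs a call. Without a call in either fit, 98 values of named genes turned sign, 20 of them with median-ratio scaling or quantile normalization, 77 with 1 library left out and 1 otherwise. Of the medians of lists 140 turned sign, 35 with the 2 scalings (none called in either fit), 85 with 1 library left out and 20 otherwise. With a call in 1 of the 2 fits 17 did. Of these, fatty acid oxidation under saline had 0.03 without labelled knockout saline replicate 2, and monocyte markers with leonurine in the labelled knockout had -0.03 without labelled knockout leonurine replicate 2 and -0.09 at a mean FPKM of at least 5. The cause was not tested. Sterol and fat synthesis with leonurine in wild type had a median of -0.54 without wild-type leonurine replicate 1, where camera's direction turned (adjusted p = 0.932), and -0.75 to -0.54 over all libraries. Interferon-induced genes without labelled knockout saline replicate 2 had 0.2 for leonurine in the labelled knockout (adjusted p = 0.0115, range -1.23 to 0.2) and 0.49 for the difference between responses (adjusted p = 0.0303, range -0.9 to 0.49). Under leonurine, fatty acid oxidation had -0.42 without wild-type leonurine replicate 2 (adjusted p = 0.0278, range -0.42 to 0.47) and cell cycle genes 0.18 without labelled knockout leonurine replicate 2 (adjusted p = 0.99, range -1.18 to 0.18). The robust prior and voom were not run for lists. Depth set little limit beside a filter of 1 FPKM.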

Other observations

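The test in this part, of a chromosome segment around Adipor2, was chosen only after the result was seen. Single markers of liver cells other than hepatocytes differed between genotypes under leonurine. Cd163, a scavenger receptor of Kupffer cells, was 14.27 ± 1.82 FPKM (SD, n = 2) in wild type and 5.325 ± 0.322 (n = 2) in the labelled knockout (log2 fold change -1.27 ± 0.15 SE, adjusted p = 0.00204 in limma), while the list of 10 Kupffer cell markers did not pass (adjusted p = 0.399). Lyve1, a marker of sinusoidal endothelium, was 10.19 ± 0.444 and 4.611 ± 0.549 (-1 ± 0.16, adjusted p = 0.00589), while the list of 13 endothelial markers did not pass (median 0.25, adjusted p = 0.107) and its members Fcgr2b, Oit3 and Kdr were called higher (1.05, 0.84 and 0.70). The calls of these 3 ended without labelled knockout leonurine replicate 1 (adjusted p = 0.0783, 0.074 and 0.119), that of Oit3 also without wild-type leonurine replicate 2 (0.0623), and that of Kdr without wild-type saline replicate 3 (0.0514), wild-type leonurine replicate 2 (0.135) or labelled knockout leonurine replicate 2 (0.057). Tnfrsf12a, the TWEAK receptor induced in injured liver, was 33.17 ± 1.88 and 4.478 ± 1.46 (-2.67 ± 0.34, adjusted p = 0.00255), while the list of 11 cell death genes that holds it did not pass (adjusted p = 0.809). The calls of Cd163, Lyve1 and Tnfrsf12a held whichever library was left out, and Ddx3y was at 0 in the labelled knockout libraries compared here.

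Dusp1, an immediate early phosphatase, fell by 1.5 on the log2 scale (± 0.19 SE, adjusted p = 0.00484) with leonurine in wild type, and Chil3, a marker of recruited macrophages, rose by 2.08 ± 0.23 (adjusted p = 0.00258). The immediate early list that holds Dusp1 did not pass there (adjusted p = 0.574). Chil3 was the 1 member called of 9 on the list of monocyte and recruited macrophage markers, which did not pass in wild type (median 0.14, adjusted p = 0.0628), and without leonurine replicate 1 its members Lyz2 and Cd68 were called lower (-1.59 and -0.96). The calls of Dusp1 and Chil3 held whichever library was left out. The difference between the responses of the genotypes did not pass for Dusp1 (1.14, adjusted p = 0.063) or Chil3 (-1.25, adjusted p = 0.0789), but passed for Chil3 without labelled knockout leonurine replicate 2 (-1.66, adjusted p = 0.0171).

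Genes that differ between the saline groups may lie in a chromosome segment carried along with the knockout allele. Of the 50 genes with the smallest p between these groups, 1 lay within 10 Mb of Adipor2, and it was Adipor2 itself, where 0.6 would lie there by chance. The count allows up to 5.3, so such a segment is neither shown nor excluded.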
